A study of Homo sapiens with 8 samples.

How the data were processed

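Single-cell EdU sequencing (scEdU-seq) was analysed in RPE-1 hTERT cells, WT and CFAP20-KO, labelled for 15 min with 10 µM EdU, fixed in ethanol and sorted into 8 plates, per the labels' protocols. The deposited files give, per the file headers, the cell, chromosome, base-pair position, signed length and genotype of each sequenced fragment. They hold positions, with no count, score or other scaled value. The genome build was GRCh38, per the submitters' processing notes; aligner, mapping filters and removal of duplicates are not given in the sources used here. The genotype of each cell was taken from the column named treatment, since the titles place both genotypes on every plate while the labels' genotype field names CFAP20-KO for all plates. Whether plates, clones or cultures were independent is not given in the sources used here.

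Each deposited fragment was taken as 1 molecule; within a plate 3.44% to 4.79% of fragments shared cell, position and direction with another. The plates held 1746074 to 4181841 fragments, of which 91.1% to 92.8% lay on autosomes. Cells with at least 1000 autosomal molecules entered the main comparisons, 304 ± 11.3 per plate (SD, n = 8). No pair of plates held the same data: over 28 pairs chi-squared per degree of freedom was 10.9 to 62.2. Gene coordinates and symbols came from a RefSeq table of the same build, which has no strand and no sequence; overlapping genes therefore share molecules, and replication direction relative to transcription is not analysed here.

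Cells were ordered by the first axis of a correspondence analysis of molecules per 500 kb bin on the autosomes, which held 18.8% of the variation, after bins under 0.1 of the median count had been left out; the gene-rich end was called early. The position of a cell is its rank, from 0 to 1. Timing of a bin or gene is the mean position of a plate's cells weighted by their molecules in it, for genes with at least 10 molecules in every plate, and for bins compared between genotypes with at least 50 molecules per plate and genotype. Track width came from distances between molecules of a cell in 5 kb steps up to 500 kb, with pairs at 400 to 500 kb as the reference. Labelled regions per cell are the genome length over 2 times the pair excess summed from 1 to 100 kb, as the median over cells. Terciles divide the ordered cells into 3 equal groups. High-count bins are the 21 bins of 200 kb with more than 3 times the median count; they held 1.84% of autosomal molecules, and 18 contain no gene.

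Single values were compared by exact two-sided sign-flip permutation over 8 plates, whose smallest possible p is 0.00781, with Benjamini-Hochberg adjustment over each family. Gene lists were fixed beforehand: common fragile sites, housekeeping, mesenchymal, neuronal, liver, blood and immune, cell cycle and replication, RNAPII elongation and repair, and histone genes. A negative-binomial count model had been planned for molecules per gene; because the files hold positions and not counts, molecules were summed per gene, plate and genotype and tested with limma voom, scaled by the total, for genes with a mean of at least 10. Timing per bin and gene was tested with limma after each library had been centred on its median. Calls use an adjusted p under 0.05. The titles state that each plate holds both genotypes, so plates pair the libraries; the deviations of the 2 genotypes of a plate correlated by 0.0167 on average over genes (-0.0472 to 0.0497, other plates -0.00241), and 2 of 8 libraries correlated best with their own plate.

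Named genes are the 10 earliest and 10 latest autosomal protein-coding genes of at least 50 kb with at least 50 molecules in every plate, the 2 earliest and 2 latest members of each list, CFAP20, and the 10 with the greatest change in each direction past the adjusted p. Members behind small counts of calls within a list, and bins, were named after their values were seen. Results on items withheld here are not reported. The order, the lists, list timing, gene density, track width and its terciles, and the comparison of molecules, position, width and density between genotypes with 1000 molecules as the minimum were chosen before the data were examined. The timing comparison between genotypes, the 5 Mb windows, the segments and the chromosome 10 stretch, labelled regions, terciles by genotype, 50 kb windows around short genes, the 5000 minimum for genotype values and the values without high-count bins were chosen after the data had been seen. Alternatives covered minimum molecules, bin sizes, cell weights, plates left out, scaling, the plate as a block and the definition of track width.

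The procedures were tested on simulated data. The order correlated with the true order by 0.950 and timing with the true timing by 0.973. All simulated cells were in S phase and had more molecules than many of the cells ordered here, so these values do not cover weakly labelled wells. Among simulated molecules per gene, 40.4% of genes changed by 1 on the log2 scale and 97.8% of those changed by 2 were found, with 6 false calls among 8804 unchanged genes. Among simulated bins, 9% of timing changes of 0.05 and 87% of those of 0.1 were found, with 4 false calls among 4985. Noise was drawn separately for each gene or bin, so differences of a library shared by many of them were not simulated. Tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.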

Results

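DNA synthesis was mapped cell by cell in RPE-1 hTERT cells, a human retinal pigment epithelial line immortalised with telomerase, in a wild-type (WT) form and with CFAP20 knocked out (KO). CFAP20 is a conserved protein of cilia and flagella, and the series title ties it to RNA polymerase II that stalls ahead of replication forks. Cells were given a 15 min pulse of 10 µM EdU, a thymidine analogue that is built into newly made DNA, and were sorted into 8 plates that each held both genotypes. The question put to the data was where, when and how densely DNA was labelled, and how this differed between the genotypes. The plates held 26148975 fragments in 3023 wells, 1594 WT and 1429 KO, and 3268622 ± 754130 fragments per plate (SD, n = 8; range 1746074 to 4181841). At least 1000 autosomal molecules were found in 2430 cells, 1290 WT and 1140 KO, and these cells entered the main comparisons. At least 5000 were found in 914 cells, 483 WT and 431 KO, which held 86.7% of all autosomal molecules. Nothing in the labels says that the plates came from separate cultures, so p-values measure only the spread between plates.

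Regions rich in genes were labelled in cells at the early end of the S-phase order, and gene-poor regions in cells at the late end, where early was set as the end with label in gene-rich DNA. Timing, the mean position of the labelled cells on a scale from 0 (early) to 1 (late), had a correlation over 5422 bins of 500 kb between plates of 0.987 on average (0.981 to 0.992, 28 pairs). The gene-rich chromosomes 17, 22 and 19 had median timings of 0.222, 0.228 and 0.251, and the gene-poor chromosomes 18 and 13 had 0.653 and 0.600. Over bins, timing and gene number had a correlation of -0.502; bins are not independent replicates. CFAP20 itself (chromosome 16, 58113592 to 58129381, GRCh38) lay in early DNA at 0.165 ± 0.0727 (SD, n = 8 plates), but held only 102 molecules over all plates, too few to compare the genotypes. Its DNA signal in any case does not check the knockout, since labelled DNA does not show a lost protein.

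Among the earliest of 3164 long, well-covered protein-coding genes were GRK4, a kinase of G protein-coupled receptors, at 0.159 ± 0.0412 (SD, n = 8), LRRC37A2 at 0.160 ± 0.0337, LOC400499 at 0.161 ± 0.0395 and TTC7A at 0.161 ± 0.0301. ARHGEF11, RAB31, a small GTPase of vesicle traffic, PDE8A, a cyclic AMP phosphodiesterase, ATL1, which shapes the endoplasmic reticulum, and CFAP92 followed at 0.165 to 0.167. LRRC37A2 has near-identical copies nearby, so its molecules are of uncertain origin. The latest were GABRB2, a GABA receptor subunit, at 0.887 ± 0.0332, FUT9, a fucosyltransferase, at 0.885 ± 0.0210, CNTN6, a neural adhesion molecule, at 0.883 ± 0.0352, EPHA7, an ephrin receptor, at 0.879 ± 0.0496 and MCTP2 at 0.879 ± 0.0244. CDH7, a cadherin, TCERG1L, ANO5, SMOC2 and FAM135B lay at 0.873 to 0.877.

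Genes at common fragile sites and neuronal genes replicated late, while cell cycle genes replicated early; mesenchymal genes were earlier than all genes but within the range of random lists of like length. The 24 measured fragile-site genes had a median timing of 0.728 ± 0.0271, later by 0.466 ± 0.0369 than all 8608 genes measured (0.262; SD, n = 8), and all 24 lay later than the median gene. Members are counted as earlier or later than the median of the timings averaged over plates, 0.246. They ran from CDH13, a cadherin, at 0.548 and PDE4D, a phosphodiesterase, at 0.561 to CNTNAP2 at 0.851 and CSMD1 at 0.866. The 20 neuronal genes had a median of 0.724 ± 0.0264, from the potassium channel gene KCNQ5, close to the median gene at 0.250, and SYT1, a calcium sensor of synaptic vesicles, at 0.370 to LRRTM4 at 0.862 and CNTN4 at 0.871. Among 10000 random lists matched by 10 groups of gene length the medians of the fragile-site and neuronal genes stood at percentiles 99.97 and 99.92. Many members are very long, such as CNTNAP2 at 2304 kb and CNTN4 at 959 kb. Length within a group was not matched, so these percentiles do not exclude length as a reason for late timing. With equal weight per cell the fragile-site and neuronal differences from all genes were smaller, 0.241 and 0.239. Liver genes lay later than all genes by 0.0762 ± 0.0386, with 3 of 9 members earlier than the median gene. The earliest were HNF4A, a hepatocyte transcription factor, at 0.187 and C3 at 0.193, and the latest UGT2B7 at 0.723 and CPS1, of the urea cycle, at 0.753. The list stood at percentile 82.2. The size of the liver difference was unstable, at 0.0484 without plate 8, 0.0282 with equal weight per cell, and 0.166 ± 0.0312 (percentile 97.7) in cells of at least 5000 molecules.

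Cell cycle and DNA replication genes were earlier than all genes by -0.0516 ± 0.0380 (11 of 14 members earlier), with RRM2 and RFC1 at 0.172 and 0.174, and POLD1 and CHEK1 at 0.375 and 0.399. Mesenchymal genes typical of this line were earlier by -0.0337 ± 0.00913 (7 of 10 members), with CD44 at 0.176, the fibronectin gene FN1 at 0.179, the integrin gene ITGB1 at 0.260 and TIMP3, an inhibitor of matrix proteases, far later at 0.752. RNAPII elongation and repair factors were earlier by -0.0181 ± 0.0170 (8 of 11 members earlier), with POLR2B at 0.199, TCEA1 at 0.202, CDC73 at 0.344 and XRN2 at 0.510. Markers of blood and immune cells lay 0.0137 ± 0.0358 later (5 of 12 members later), from RUNX3 at 0.160 and CSF1R at 0.178 to FLT3 at 0.652 and IKZF1 at 0.699. Over the 7 lists with enough members, the exact two-sided sign-flip permutation test over plates gave p = 0.00781, the smallest 8 plates allow, and an adjusted p of 0.0109 for fragile-site, neuronal, liver, cell cycle and mesenchymal genes. It gave an adjusted exact p of 0.0273 for RNAPII factors, higher in 1 of 8 plates, and of 0.328 for blood and immune genes, earlier in 4 of 8 plates. Against random lists of like length the cell cycle genes stood at percentile 2.43, but the mesenchymal genes at 42.6 and the RNAPII factors at 47.0, well inside the range of random lists. The RNAPII call was lost without plates 1, 2, 3, 4, 5 or 6 in turn (-0.0173, -0.0168, -0.0169, -0.0139, -0.0169 and -0.0195). In the 914 cells of at least 5000 molecules, blood and immune genes were later than all genes by 0.0660 ± 0.0273 (adjusted exact p = 0.00781). There the fragile-site and neuronal differences were 0.339 and 0.342. Cell cycle genes lay at -0.0896 ± 0.0376, mesenchymal genes at -0.0786 ± 0.0288 and RNAPII factors at -0.0564 ± 0.0332, each earlier in 8 of 8 plates, at percentiles 15.4, 18.9 and 19.4 of random lists.

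Most housekeeping and histone genes are too short to be measured by their bodies, with 1 of 25 housekeeping genes, NPM1, at 0.409 ± 0.0911 and 0 of 25 histone genes measured. In 50 kb windows, 21 housekeeping genes were earlier than all genes by -0.0345 ± 0.0137 (SD, n = 8 plates; adjusted exact p = 0.00781), at percentile 9.5 of random lists of like length. All 25 histone genes were late in such windows, by 0.480 ± 0.0364 (adjusted exact p = 0.00781), but they all lie on chromosome 6 and are not independent places.

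**Figure D1:**
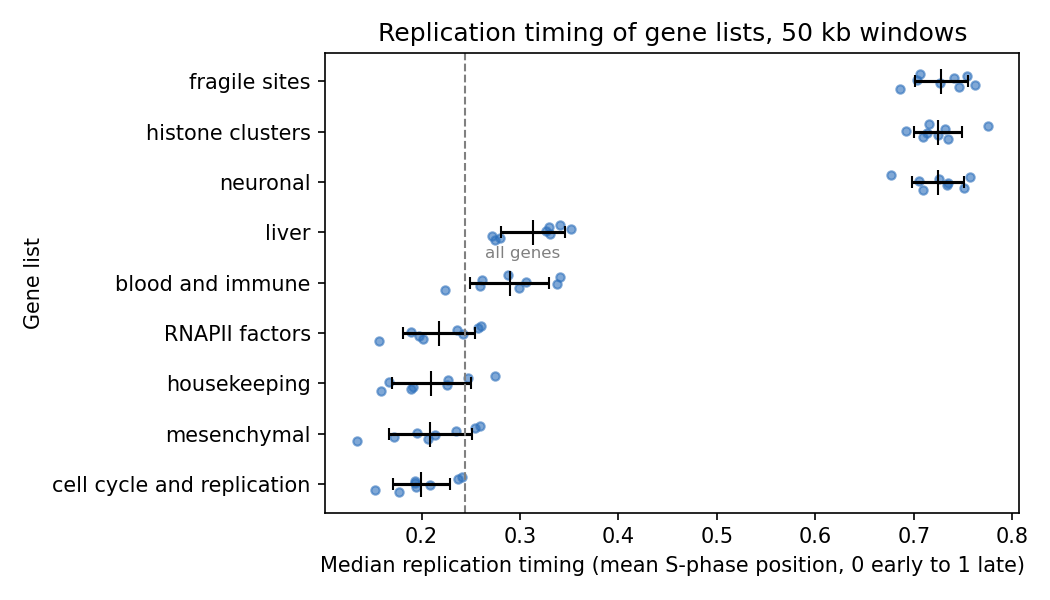
Median replication timing of each gene list in windows of at least 50 kb (x axis, mean S-phase position from 0, early, to 1, late), with 1 point per plate and bars for the mean and SD over 8 plates; the dashed line marks the median of all genes, 0.244. Fragile-site, histone and neuronal genes lie at 0.728, 0.724 and 0.724, and the other 6 lists lie between 0.200 and 0.313.

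Protein-coding gene bodies held fewer labelled molecules per kb than the rest of the autosomes. The log2 ratio was -0.17 ± 0.06 (SD, n = 8), below 0 in 8 of 8 plates (exact sign-flip permutation, two-sided, p = 0.00781), and -0.08 with equal weight per cell. Against flanks of 50 kb that hold no gene the direction turned, with 0.05 on the log2 scale (exact p = 0.00781).

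Labelled molecules of a cell lay in tracks, and these were narrowest in early S phase. Track width, the distance at which the excess of molecule pairs fell to 50% of its value at 5 to 10 kb, was 15.6 ± 0.247 kb over all cells (SD, n = 8). It was 15.0 ± 0.321 kb in the early tercile of the order, 16 ± 0.563 kb in the middle and 15.8 ± 0.287 kb in the late tercile. Cells of the middle tercile held few molecules, on average 4847 in WT and 3651 in KO. The means were 12450 and 9636 in the early and 15830 and 11332 in the late tercile. Whether all cells of the middle tercile were in mid S phase was not tested. Middle and late tracks were wider than early ones by 1.02 ± 0.568 and 0.844 ± 0.473 kb, each in 8 of 8 plates (exact sign-flip permutation, adjusted p = 0.0117 for both), and late and middle tracks differed by -0.172 ± 0.580 kb (adjusted exact p = 0.422). Without chromosomes 10 and 12 both differences from early tracks, 0.660 and 0.292 kb, missed the test after adjustment (adjusted exact p = 0.0703 and 0.0859). Without 21 bins of 200 kb that hold more than 3 times the median number of molecules they were far larger, 3.95 and 4.68 kb (adjusted exact p = 0.0117 for both). In cells of at least 5000 molecules they were 2.00 ± 0.551 and 1.36 ± 0.730 kb, and late minus middle was -0.639 ± 0.309 kb, below 0 in 8 of 8 plates (adjusted exact p = 0.00781 for all 3). Without the high-count bins in these cells, late minus middle turned to 2.98 kb (adjusted exact p = 0.00781). The order of middle and late widths thus depends on those bins.

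KO cells carried fewer labelled molecules than WT cells of the same plate. The mean was 11051 ± 2709 molecules per WT cell and 8232 ± 1834 per KO cell (SD, n = 8), a log2 difference of -0.42 ± 0.21 (1.33-fold), lower in KO in 8 of 8 plates. In cells of at least 5000 molecules the means were 26082 ± 4825 and 18271 ± 2854, a log2 difference of -0.50 ± 0.15 (1.42-fold). KO cells lay slightly later in S phase, at a mean position of 0.518 ± 0.0214 against 0.485 ± 0.0198 in WT, later in 8 of 8 plates. In cells of at least 5000 molecules the positions were 0.529 ± 0.0372 and 0.473 ± 0.0434, later in KO in 7 of 8 plates (adjusted exact p = 0.0208). In the early tercile 15.6 ± 3.54 KO and 22.5 ± 5.71 WT cells of at least 5000 molecules were found per plate, while the share of such cells did not separate the genotypes (38.2% ± 7.31 in KO and 37.3% ± 6.65 in WT, exact p = 0.766). The exact sign-flip permutation test over plates gave an adjusted p of 0.0104 for molecules and for position. The early tercile had an adjusted exact p of 0.0469, with more KO than WT cells in 1 of 8 plates. That test compares numbers of cells, and KO had fewer wells (1429 against 1594) and fewer cells of at least 5000 molecules (431 against 483). The share of each genotype's cells in the early tercile was not tested. The ratio of gene bodies to the rest of the genome was -0.19 in KO and -0.16 in WT on the log2 scale, with an adjusted exact p of 0.25. A permutation that ignores the plates gave an adjusted p of 0.0694 for molecules per cell, and with a minimum of 300 molecules position missed the test (0.0263, adjusted exact p = 0.0938).

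Tracks were wider in KO than in WT cells, with the greatest difference in early S phase. Over cells of at least 1000 molecules the width was 15.9 ± 0.177 kb in KO and 15.4 ± 0.349 kb in WT, a difference of 0.490 ± 0.281 kb in 8 of 8 plates (SD, n = 8). Over cells of at least 5000 molecules it was 16.3 ± 0.227 kb and 15.0 ± 0.327 kb, a difference of 1.34 ± 0.339 kb, also in 8 of 8 plates. There, early S-phase tracks measured 15.9 ± 0.706 kb in KO and 13.5 ± 0.393 kb in WT, middle tracks 17.2 ± 0.314 and 15.9 ± 0.333 kb, and late tracks 16.3 ± 0.453 and 15.6 ± 0.479 kb. The same cells held fewer labelled regions in KO, an estimate from close molecule pairs, with 4609 ± 251 per cell against 5803 ± 197 in WT, a log2 difference of -0.33 ± 0.10 in 8 of 8 plates (exact p = 0.00781). The adjusted exact sign-flip p for width was 0.0104 at 1000 molecules and 0.0156 at 5000, and each tercile had an adjusted exact p of 0.00781 at 5000, wider in KO in 8 of 8 plates. With 1000 molecules as the minimum, the difference in width was lost without chromosomes 10 and 12 (0.136 kb, adjusted exact p = 0.359) and with a minimum of 300 (0.385 kb, adjusted exact p = 0.125), the middle tercile turned to -0.787 ± 0.779 kb (adjusted exact p = 0.0313), and regions per cell did not pass (log2 -0.10, exact p = 0.711). Without the high-count bins the difference in width at this minimum was 1.16 kb (adjusted exact p = 0.0104). At 5000 molecules it was 1.16 kb without chromosomes 10 and 12 (exact p = 0.00781), and 2.08 ± 0.308 kb without the high-count bins. Without those bins the early effect exceeded the middle by 0.816 ± 0.941 kb and the late by 1.2 ± 1.31 kb (adjusted exact p = 0.0820 for both). The high-count bins include some of chromosome 10 that held more molecules in WT than in KO. From 36400001 to 36600000 the means were 5.17 and 1.35 times the median bin in cells of at least 5000 molecules. Leaving these bins out thus does not act alike on both genotypes.

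**Figure D2:**
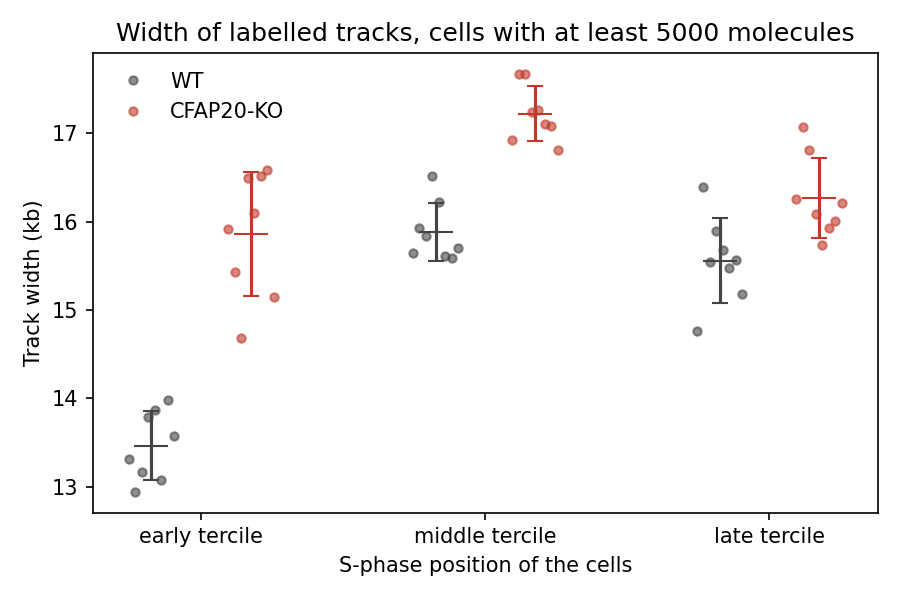
Track width in kb (y axis) in the early, middle and late terciles of the S-phase order (x axis) for WT (grey) and CFAP20-KO (red) cells of at least 5000 molecules, with 1 point per plate and bars for the mean and SD over 8 plates. The genotypes differ by 2.40 kb in the early, 1.34 kb in the middle and 0.703 kb in the late tercile.

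Several long stretches of the genome gave fewer labelled molecules in KO than in WT cells. They were chromosome 7 from 65000001 to 75000000 (log2 -0.64 ± 0.15) and from 105000001 to its end (-0.68 ± 0.05), chromosome 20 from its start to 25000000 (-0.61 ± 0.08) and chromosome X from 150000001 to its end (-0.63 ± 0.27; SD, n = 8). Each was lower in KO in 8 of 8 plates. Each is a run of 2 or more adjacent 5 Mb windows past the limma test, with or without the plate as a block, with a log2 of at most -0.4; as they were picked by this difference, no separate p is given. In KO cells of at least 5000 molecules these segments held 60.2% of the WT share. Chromosome 19 from 55 Mb on was lower in a single window (log2 -0.70), and chromosome 10 near its centromere had the lowest ratio of KO over WT (log2 -1.09). There, 34800001 to 37800000, the longest run of 200 kb bins lower in KO in every plate, held 3.76 ± 0.895 times the molecules of a median bin in WT and 1.29 ± 0.0875 times in KO, a 2.92-fold ratio (SD, n = 8; cells of at least 5000 molecules). The bin just before it held 1.19 times in WT and 0.909 times in KO. This stretch thus stood above the median bin mainly in WT, and over its whole length KO was not depleted below it. In its first bins, from 34800001 to 35600000, KO lay slightly under the median bin, at 0.703 to 0.982 times, and WT at 2.28 to 3.21 times. In all, 37 of 602 windows fell and 25 rose in KO (limma voom), or 78 and 63 with the plate as a block. The windows that rose numbered 12, 13, 14 and 14 without plates 1, 2, 3 and 5.

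**Figure D3:**
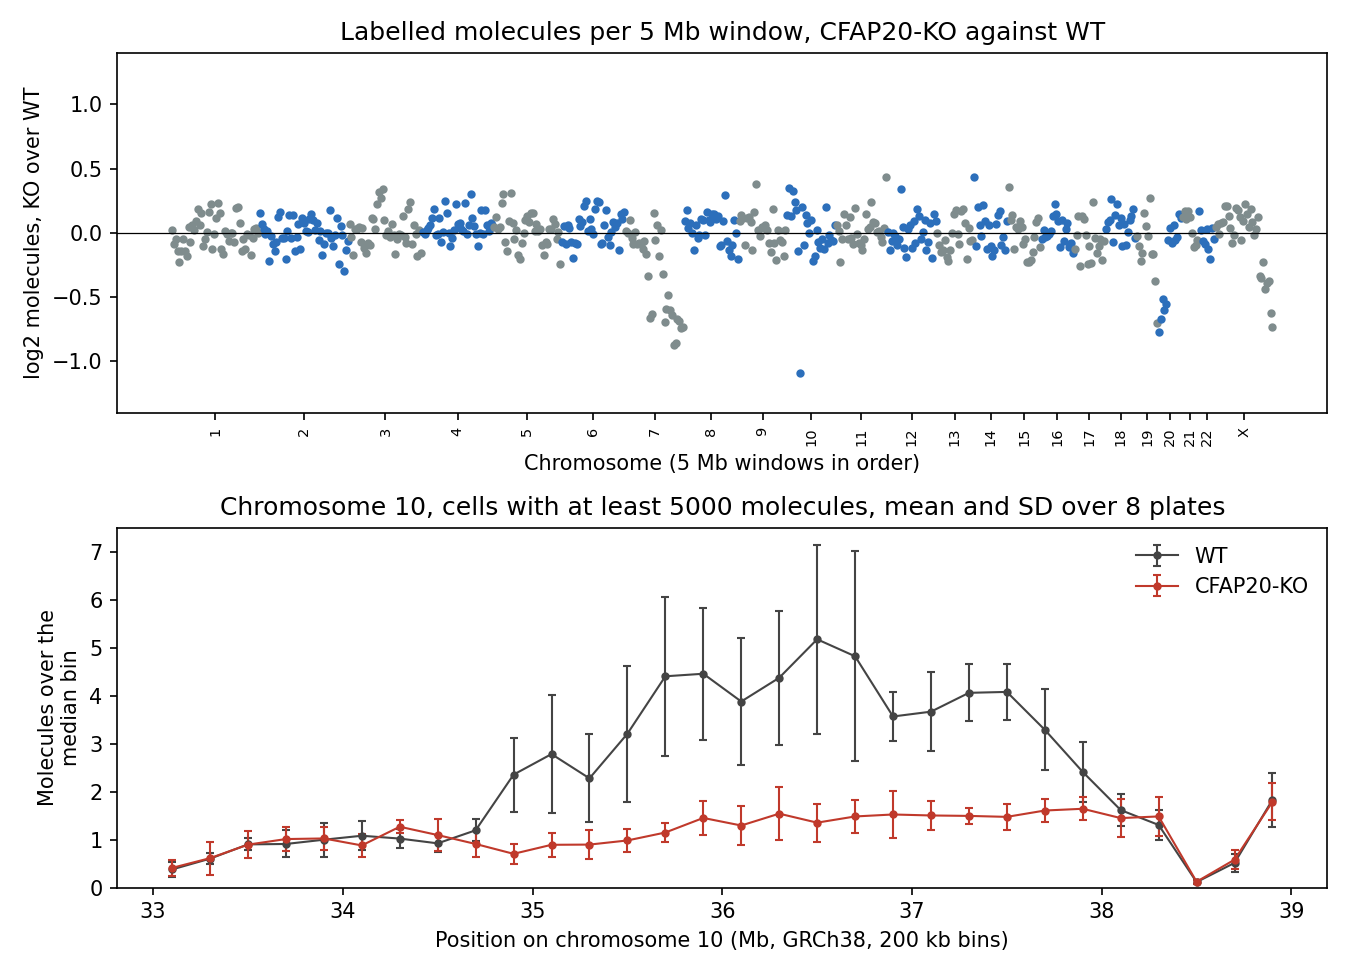
Upper panel, log2 ratio of KO over WT molecules (y axis) in 5 Mb windows along the chromosomes (x axis), 1 point per window with colours alternating by chromosome. Lower panel, molecules per 200 kb bin over the median bin (y axis) along chromosome 10 in Mb (x axis) in cells of at least 5000 molecules, mean and SD over 8 plates for WT (grey) and KO (red); from 34800001 to 37800000 the means are 3.76 and 1.29.

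Of 9265 genes tested, 104 held fewer and 19 more molecules in KO (limma voom), or 125 and 41 with the plate as a block. Of the 104, 76 lay in the segments above, where 271 genes were tested and 98.9% were below 0 (median log2 -0.72). The genes that fell most were SIGLEC5, a sialic acid receptor of immune cells (log2 -2.83 ± 0.45 SE, limma adjusted p = 2.25e-05), and FLNA, the actin crosslinker filamin A on chromosome X (-1.81 ± 0.42). FPR3, a formyl peptide receptor (-1.75 ± 0.44), VPS16, of endosomal sorting (-1.72 ± 0.42), and SPACA6 (-1.67 ± 0.41) were next. CIMIP2C, C7orf33, RNF24 and ZSCAN18 followed at -1.63 to -1.53. SIGLEC5, FPR3, SPACA6 and ZSCAN18 lie on chromosome 19 beyond 50 Mb, and VPS16 and RNF24 on chromosome 20. All of these had means of 10 to 15.2 molecules per plate and genotype, and SIGLEC5 has a near-identical neighbour, so its molecules are of uncertain origin. CUL2, the cullin 2 scaffold of a ubiquitin ligase, lies in the chromosome 10 stretch that stood high in WT. It was lower in KO by 1.54 ± 0.22 with 141 molecules. Its neighbours CREM, CCNY and ANKRD30A, named after their values were seen, were lower in KO by 1.00, 1.27 and 1.32.

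The genes that rose in KO did so by less. MALRD1 (log2 0.60 ± 0.11 SE, limma adjusted p = 0.000267), SFMBT2, a Polycomb-group protein (0.61 ± 0.16), and CELF2, an RNA-binding splicing regulator (0.48 ± 0.10), all lie on the short arm of chromosome 10. NOVA1, a neuronal splicing factor (0.63 ± 0.16), CYP7B1, an oxysterol hydroxylase (0.60 ± 0.16), NOL4 (0.55 ± 0.14) and VAV3 (0.49 ± 0.12) rose as well. VPS26B (1.30 ± 0.34), AIMP1 (1.14 ± 0.30) and FMO2 (1.06 ± 0.29) had the largest values, with 17.5 to 18.5 molecules each. With the plate as a block VPS26B and FMO2 had limma adjusted p values of 0.129 and 0.0544. In cells of at least 5000 molecules AIMP1, FMO2, NOVA1 and CYP7B1 did not pass (limma adjusted p = 0.0689, 0.0625, 0.0523 and 0.0738), with log2 values of 1.19, 1.13, 0.69 and 0.63. The genes that rose numbered 8, 7, 10 and 10 without plates 1, 2, 5 and 7, and 4 where both genotypes were given the same molecules in each tercile of S phase.

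Of the lists, fragile-site genes moved in both directions. Of 25 measured, 5 fell, namely EXOC4, CNTNAP2, IMMP2L and AUTS2 on chromosome 7 and MACROD2 on chromosome 20, all inside the segments, and 2 rose, MAGI2 and FHIT. Adjusted over the list alone, 5 fell and 11 rose, and with the plate as a block 5 fell and 5 rose. Of 20 neuronal genes 3 rose, CNTN5, PTPRD and CADM2, and 0 fell. Adjusted over the list alone, NRXN3 joined them and 4 rose. Fragile-site and neuronal genes replicate late and KO cells lay later in S phase, so these rises cannot be told apart from cell position. With the same molecules in each tercile for both genotypes, 4 genes rose and 102 fell over all genes, against 19 and 104 without this. The lists were not counted in that setting. Of 12 mesenchymal genes 1 fell, FLNA, and adjusted over the list alone the count was 1. With limma voom, 0 of 12 blood and immune, 16 cell cycle, 13 RNAPII, 11 liver and 2 housekeeping genes passed, and 2, 1, 1, 2 and 0 had an unadjusted p under 0.05. Adjusted over the list alone, these counts stayed at 0 except for 1 liver gene, ADH1B, with a log2 of 1.05; histone genes had 0 members with enough molecules. The median log2 of no list passed the exact sign-flip permutation test after adjustment, with the lowest adjusted p, 0.219, for neuronal genes (0.15 ± 0.15, higher in 6 of 8 plates).

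The timing profiles of the genotypes had a correlation of 0.965 over bins, yet many single bins replicated earlier or later in KO. Of 5185 bins of 500 kb, 1316 were later and 721 earlier in KO (limma on timing centred per library); with all libraries set to the same distribution the counts were 1034 and 1033, and with equal weight per cell 386 and 295. The bin on chromosome 14 from 65500001 to 66000000 moved from 0.597 ± 0.0201 in WT to 0.287 ± 0.0399 in KO (SD, n = 8; limma adjusted p = 7.89e-18). Bins starting at 96000001 of chromosome 14, 77000001 of chromosome 5 and 73000001 of chromosome 15 were earlier in KO by -0.259, -0.252 and -0.236. The adjacent bins from 79000001 to 80000000 of chromosome 7 were later in KO by 0.237 and 0.281, and those starting at 36500001 of chromosome 15, 79000001 of chromosome 14 and 81500001 of chromosome 3 by 0.220, 0.217 and 0.215. In cells of at least 5000 molecules the shifts were smaller, with -0.199 for the bin at 65500001 of chromosome 14 and 0.165 for that at 79500001 of chromosome 7. Calls in both directions were most frequent in rather late DNA, with 417 later and 339 earlier of 1296 bins between 0.452 and 0.716. Among the earliest 1297 bins 381 were later and 0 earlier (limma; 1 earlier at an unadjusted p under 0.05). These bins lie at the low end of the scale, from 0.172 to 0.245. Their median shift over plates, 0.0407 ± 0.0508 (later in 7 of 8 plates), did not pass the exact sign-flip permutation test (p = 0.0703, adjusted p = 0.281). Before centring, KO bins were later by 0.0239 ± 0.0243 in the median (6 of 8 plates, exact sign-flip p = 0.0469).

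**Figure D4:**
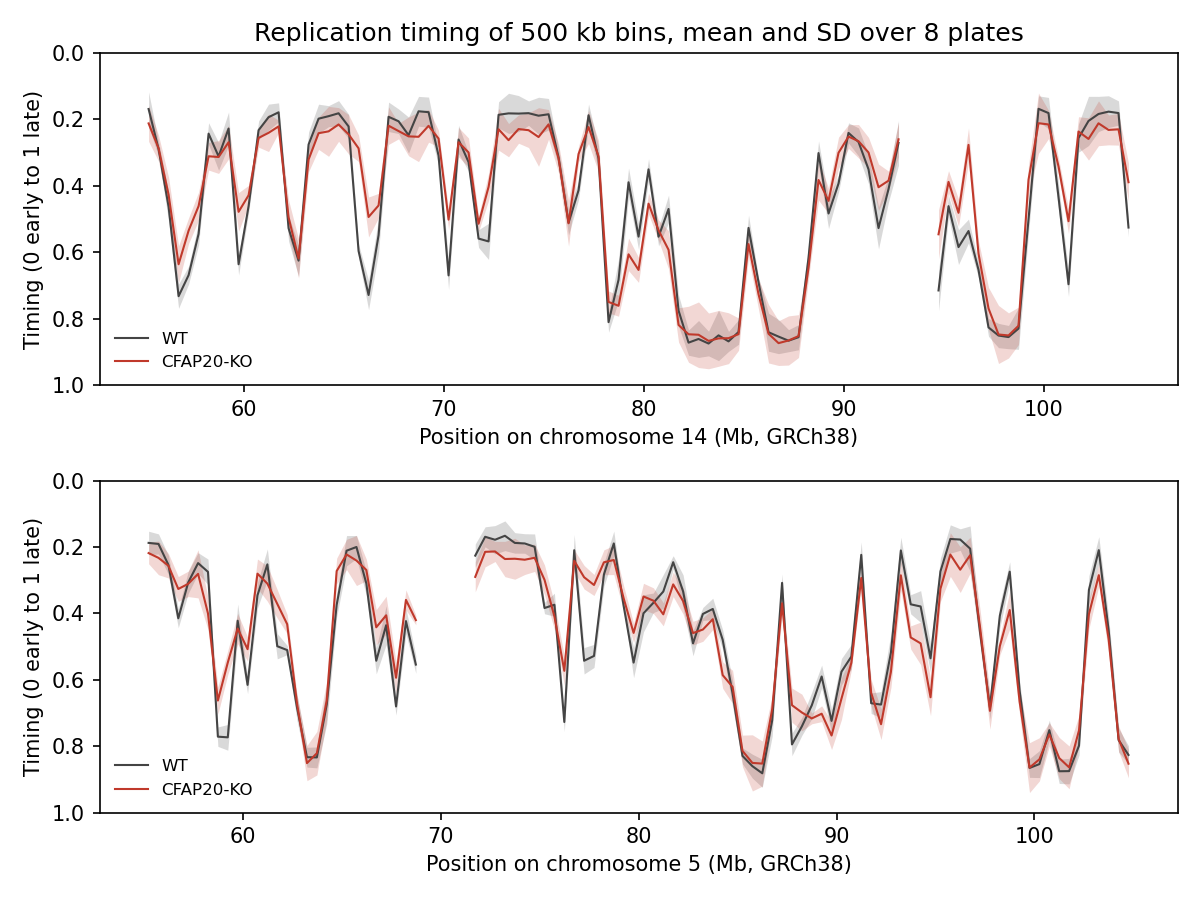
Replication timing (y axis, 0 early at the top to 1 late) of 500 kb bins along parts of chromosomes 14 and 5 (x axis, Mb, GRCh38) in WT (grey) and CFAP20-KO (red), lines for the mean and bands for the SD over 8 plates; gaps are bins not measured in every plate. In the bin of chromosome 14 starting at 66000001 WT lies later than KO, at 0.729 against 0.494.

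Among genes, PROX1, a homeobox regulator of lymphatic and liver fate, moved most, from 0.732 ± 0.0725 in WT to 0.325 ± 0.123 in KO (SD, n = 8; limma adjusted p = 1.41e-06). HOXA3, a homeobox gene of body patterning, WDR41, PDE8B, a cyclic AMP phosphodiesterase, HCN4, a pacemaker channel, MUCL1, LOC124903571, SLC22A15, ATG2B, a lipid transfer protein of autophagy, and GALNT18 were earlier in KO by -0.341 to -0.313. PRKAA2, a catalytic subunit of the energy sensor AMPK, was later by 0.271 ± 0.0318 (SE), followed by DTHD1, SLCO1A2, an organic anion transporter, GYS2, the liver glycogen synthase, and TRHR, the receptor of thyrotropin-releasing hormone, at 0.242 to 0.226. PTPN12, GBE1, the glycogen branching enzyme, STON2, PGM5 and PLCZ1 were later by 0.213 to 0.201. In cells of at least 5000 molecules the shifts that could be measured were smaller, such as 0.174 for PRKAA2, 0.127 for STON2, -0.199 for WDR41, -0.179 for PDE8B and -0.173 for GALNT18; PROX1 and HOXA3 were not measured there. Of 4610 genes 632 were earlier and 221 later (limma); without centring 373 were earlier and 621 later, and with equal distributions 549 and 454, and in cells of at least 5000 molecules 592 and 369, so the balance of directions rests on the scaling.

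Members of the lists moved in both directions between the genotypes. Of 24 fragile-site genes NAALADL2, MAGI2 and IMMP2L were later and PDE4D and EXOC4 earlier in KO. Of 20 neuronal genes NLGN1, GABRB1 and NRXN3 were later and NTM, OPCML and GRIN2B earlier. Adjusted over the list alone the counts were again 3 and 2, and 3 and 3. With the plate as a block they were 1 and 2 for fragile-site and 2 and 3 for neuronal genes. Of 6 blood and immune genes BACH2, IKZF1 and FLT3, regulators and a receptor of blood cell formation, were earlier, and adjusted over the list alone IKZF3 was later as a further call. CHEK1, a checkpoint kinase, was the 1 call of 3 cell cycle genes and was earlier. MET, a growth factor receptor, was the 1 of 5 mesenchymal genes and was later. These counts were the same adjusted over the list alone. The 5 RNAPII factors gave 0 calls with limma over all genes, adjusted over the list alone or at an unadjusted p under 0.05, and housekeeping and histone genes had no member with enough molecules in each genotype. The medians of the member differences did not pass the exact sign-flip permutation test after adjustment. The lowest adjusted exact p, 0.328, was shared by blood and immune genes (-0.0352 ± 0.0453) and liver genes (-0.0201 ± 0.0276), each later in 1 of 8 plates. Taken as a difference of list medians, liver genes (-0.215) and blood and immune genes (-0.0598) passed (adjusted exact p = 0.0273 for both).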

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

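The comparison of track widths between terciles by genotype, the labelled regions, the mitochondrial share and the test on S-phase position were chosen only after the results were seen. The effect of the knockout on track width differed between terciles of S phase by a test of the difference itself. With 1000 molecules as the minimum, KO minus WT was greater in the early than in the middle tercile by 2.68 ± 0.774 kb (8 of 8 plates) and than in the late tercile by 1.55 ± 0.404 kb (8 of 8 plates; adjusted exact p = 0.0117 for both), and middle minus late was -1.13 ± 0.841 kb (higher in 1 of 8 plates, adjusted exact p = 0.0156). With 5000 molecules the differences were 1.05 ± 0.762 kb (7 of 8 plates), 1.69 ± 0.970 kb (8 of 8) and 0.640 ± 0.493 kb (7 of 8), each with an adjusted exact p of 0.0234. Without high-count bins they were 0.816 ± 0.941, 1.2 ± 1.31 and 0.384 ± 1.02 kb and none of the 3 passed (adjusted exact p = 0.0820, 0.0820 and 0.406), with a wider spread between plates.

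A pattern to weigh is the wider tracks of KO cells of at least 5000 molecules, 1.34 ± 0.339 kb in 8 of 8 plates. With each cell thinned to 5000 molecules the difference was 1.36 ± 0.470 kb (8 of 8 plates), so the number of molecules read did not by itself set the width. Random thinning keeps the ratio of close to distant pairs on average. It thus cannot address differences in labelling or background that go with molecules per cell, and these stay open. The later S-phase position of KO cells is argued against as the whole cause, since the mean over terciles of equal weight was 1.48 ± 0.266 kb (8 of 8 plates). A difference in culture or clone between the genotypes stays open, as the labels name none. Faster or longer synthesis per region in KO cells is a hypothesis that may fit these values but was not tested, and width and regions per cell come from the same molecule pairs.

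Of 24 groups of plates searched for a plate far from the others, 3 held one, where chance gives about 1 in 20 groups, or 1.2. Track width in KO cells of at least 1000 molecules was 16.3 kb on plate 2 and 15.7 to 16 kb on the others. Labelled regions were 5373 per WT cell on plate 6 against 5711 to 5978 on the others. They were 5181 per KO cell on plate 8 against 4368 to 4646 on the others. In data outside the main measurement, mitochondrial DNA gave 0.199% ± 0.0293 of fragments in KO and 0.152% ± 0.00807 in WT cells of at least 5000 molecules (higher in KO in 8 of 8 plates, exact p = 0.00781). Mitochondrial fragments per cell were 38.7 ± 3.58 and 42.6 ± 6.64 (exact p = 0.0703).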

How the results depend on the processing

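Alternatives for timing, lists, density and track width over all cells were mostly planned; those for genotype effects, except the block, the unpaired test and the filter, and the 50 kb windows and high-count bins were chosen only after the results were seen. Of the main results under all alternatives, 387 values kept direction and side of the threshold, 30 lost the call, 6 gained one, 12 turned and 27 moved; the cause was not tested except where stated.

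With 5000 molecules as the minimum, blood and immune genes lay 0.0660 later than all genes, late minus middle width was -0.639 kb, KO minus WT width in the middle tercile turned to 1.34 kb, 114 cells per plate had 22399 molecules per cell, and 369 genes were later in KO; with 1000, labelled regions gave a log2 of -0.10. With 300, 364 cells per plate entered, and KO minus WT was 0.0263 for position, 0.385 kb for width and 0.397 kb in the late tercile, none past the test. Without chromosomes 10 and 12, width was 15.1 kb, middle minus early 0.660, late minus early 0.292, and KO minus WT 0.136 kb, or -0.543 and -0.210 kb in the middle and late terciles. Without high-count bins, width was 16.9 kb, middle minus early 3.95, late minus early 4.68, late minus middle 0.727, and KO minus WT -0.256 and 0.235 kb in the middle and late terciles; with 5000 molecules as well, 16.2, 2.98 and, for the middle tercile, 1.61 kb.

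At 10% of the pair excess, width was 58.9 kb, middle minus early 6.36 and late minus middle 14.2; in 10 kb steps width was 23.8 kb and late minus middle 0.189. The width thus depends on its definition by construction. RNAPII factors missed the test with 1 Mb bins (-0.0175), equal weight per cell (-0.0182) and an order from the other chromosomes (-0.0178). Equal weight also gave a plate correlation of 0.966, fragile-site and neuronal genes at 0.241 and 0.239, gene density at -0.0772 on the log2 scale, blood and immune genes at 0.0276, and 386 later and 295 earlier bins; 50 kb windows gave 0.0449 for blood and immune genes. Liver genes kept their call but ranged from 0.0282 (equal weight) to 0.166 (5000 molecules). Gene density against 50 kb flanks turned to 0.0471 on the log2 scale, and without high-count bins to 0.0473. As differences of list medians, KO minus WT timing was -0.0598 for blood and immune and -0.215 for liver genes, past the test, and turned to 0.0122 for cell cycle, 0.0199 for fragile-site and -0.0351 for RNAPII genes.

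With the plate as a replicate block, 41 genes and 63 windows rose and 78 windows fell; VPS26B and FMO2 lost their calls (AIMP1, FMO2, NOVA1 and CYP7B1 with 5000 molecules), fragile-site calls changed as reported, and no other count of calls over all genes, windows or bins moved by more than 1.5 times. The same molecules per tercile left 4 genes higher. Timing without centring gave 621 later and 373 earlier genes, and equal distributions 454 later. The unpaired permutation left molecules per cell at a log2 of -0.42 with an adjusted p of 0.0694.

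Leaving out 1 plate at a time gave 0.0484 at the lowest for liver genes (without plate 8), -0.0351 to -0.0139 for RNAPII factors (lost without plates 1 to 6), -0.910 to -0.575 kb for the middle tercile (lost without 2, 3, 4, 5 or 8), 0.252 to 0.40 kb for the late tercile (lost without 3, 6, 7 or 8), 7 to 28 genes higher and 12 to 32 windows higher. With 7 plates the smallest exact p is 0.0156. Replication direction relative to transcription and its alternatives, density per cutting site, DESeq2 itself and the TMM scaling and filter of edgeR were not run. Size factors by the median of ratios, used within limma voom, gave 18 genes higher and 72 lower in KO. For windows they gave 26 higher and 35 lower. Depth limits most short genes, including CFAP20, to too few molecules for a comparison.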

Other observations

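Chosen only after the results were seen were the list values between genotypes in 50 kb windows, the shared positions, the share of bins in segments, the tests of replication time in the segments by chromosome, the test with equal distributions and the splits for molecules per gene. The median timing of histone genes of the chromosome 6 cluster, measured in 50 kb windows, lay nearer to the median gene in KO than in WT cells. The values here are differences of list medians, not medians of the member differences. The median of the 21 members measured in both genotypes was later than all genes by 0.433 in WT and 0.309 in KO, a difference of -0.124 ± 0.0655 (SD, n = 8; exact sign-flip permutation, adjusted p = 0.0313). In the same form blood and immune genes gave -0.0576 ± 0.0410 (10 members, adjusted exact p = 0.0313), and liver genes, at -0.0488 ± 0.0496 (10 members), did not pass (adjusted exact p = 0.104). By gene bodies, the median of the member differences of blood and immune genes was -0.0352 ± 0.0453 and did not pass (adjusted exact p = 0.328); this form was not run in 50 kb windows. The histone genes are neighbours and share windows, so they are not independent members.

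Fewer molecules in KO in the segments of chromosomes 7, 20 and X form a pattern that spans many genes. Another replication time is argued against for chromosomes 7 and 20, since it would move molecules between terciles, while the log2 ratio was still -0.69 ± 0.10 in the tercile nearest 0 (lower in 8 of 8 plates); their bins, with a median timing difference of 0.0107 ± 0.0275, decide nothing for X, which has no timing bins. On X the ratio was -0.17 ± 0.23 in the early (lower in 6 of 8 plates), -0.31 ± 0.24 in the middle and -1.26 ± 0.46 in the late tercile. Another time and a difference in copies thus both stay open there. For all segments, a ratio of KO over WT does not tell a loss in KO from a gain in WT. Fewer DNA copies in KO than in WT cells cannot be told apart from other differences in labelling. The summed ratio was -0.676 ± 0.0967 in the tercile nearest 0 and -0.70 and -0.84 in the others. This met the outcome set beforehand for fewer copies. In wells of 1000 to 3000 molecules, however, the ratio was only -0.12 ± 0.08. The rule was made more cautious, by taking these wells into account, after that value had been seen. Spill of labelled DNA into those wells stays open too: their 20 kb profiles correlated with labelled cells of the other genotype less on the same plate than on other plates (-0.0163 ± 0.00554, 0 of 8 plates higher), the outcome set beforehand as absence of spill, but exact positions were also shared less within a plate (a ratio of 0.887), so sharing is depleted within plates, which could hide spill.

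Bins that replicated at another time in KO, 2037 in all, form a further pattern. With the same molecules of both genotypes in each of 10 steps of S phase 1671 bins were called, 1528 of them shared, and with the same molecules per cell and all cells ordered again 1901, with 1786 shared, which argues against the spread over S phase and against depth as the whole cause. Equal weight per cell left far fewer called bins, 386 later and 295 earlier, so the number of calls depends on how cells are weighted. With the same distribution of timing values in all libraries 2067 were called, 1658 shared, which argues against a narrower range of values in KO. Of the called bins 4.47% lay in the segments. These hold only 163 of the 5185 bins, so most calls could not have lain there in any case. The directions depend on scaling, so which way the balance goes stays open. A local change of replication time in this KO line is a hypothesis that may fit; clone, culture and copy number elsewhere were not tested.

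Among 100 splits of the 16 libraries, 1, the real one, gave as many calls for molecules per gene (123, highest other 58), for timing of bins (2037, highest other 822) and for timing of genes (853, highest other 321). This argues against a random assignment of libraries to genotypes for these counts. Such splits cannot address chance differences between clones or cultures, since every library of a genotype may share them. For 5 Mb windows 3 splits gave as many as the real 62, and the highest other gave 117. The share lies under 0.05, but a split other than by genotype thus gave more calls, and the reason was not tested. Among 100 splits that exchange genotypes within plates, the real one gave the most calls in each case, with the highest others at 67 genes, 41 windows, 1102 bins and 376 genes by timing.

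In wells of 1000 to 3000 molecules, 27.9% ± 6.18 of molecules lay at the exact position and direction of a molecule of a labelled cell on the same plate, against 31.3% ± 6.22 for wells of other plates, a ratio of 0.887 ± 0.0496, lower in 8 of 8 plates (exact p = 0.00781).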
